A study of Bos taurus with 8 samples.

How the data were processed

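Single cells of 8 individual cattle embryos produced in vitro were profiled by PIP-seq, with 1 library per embryo, 4 embryos of day 12 and 4 of day 16 after fertilization. The deposited values were integer UMI counts per gene and barcode, per the file headers, with a list of barcodes and of 38001 features for each library. Aligner, counting program, genome build, annotation release, sequencer settings and any upstream filtering are not given in the sources used here. The barcode lists were checked and held 43566 to 196370 barcodes per library, most with few UMIs, so no cell filter had been applied. Symbols came from the deposited feature list, in which 17715 features had only an identifier, and these were tested but not named. Day labels were taken from the sample descriptions. Embryos were numbered within day in the order of the series. No paired analysis was possible because the labels link no day-12 embryo to a day-16 embryo. No 2 libraries were copies of each other, with correlations of log2 CPM plus 1 between 0.830 and 0.972.

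A barcode was called a cell at 200 or more detected genes and at most 20% of UMIs from the 13 mitochondrially encoded genes. Doublets predicted by scrublet (scanpy 1.11.5) ranged from 0 to 31.0% per library with no stable threshold, so none was removed in the values reported. Their removal had been planned where scrublet worked, so keeping them was a choice made after the data were seen. Predicted doublets made up 22.2%, 11.2%, 31.0% and 27.6% of called cells in day-12 embryos 1 to 4. In day-16 embryos 1 to 4 they made up 0.370%, 15.5%, 4.84% and 0%, so their removal mostly takes day-12 cells. Called cells were log-normalised, reduced to 2000 variable genes and 10 principal components, linked to 15 neighbours and clustered by Leiden at resolution 1 (igraph 0.11.9, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). A class with at least 5 markers that reached 50 CPM in some cluster was scored by the mean of each marker's CPM relative to its highest cluster. A cluster took the class of the highest score if this was at least 0.3 and 1.3 times the next. In addition, at least 3 markers had to have a UMI, no other class to have more markers among the 10 genes of highest fold, and 1 embryo to hold at most 90% of its cells. The fold added 10 CPM, and clusters much shallower than their embryos also needed a marker among those 10 genes. This naming rule replaced an earlier one after the clusters had been seen, so class names are not blind to the data. Of the markers listed, 19 of 21 for trophoblast, 22 of 22 for hypoblast, 15 of 17 for epiblast, 18 of 18 for mesoderm, 13 of 13 for cumulus and 11 of 12 for blood, immune and endothelial cells were found, and the last 3 classes named no cluster.

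UMIs were summed over called cells of each embryo, and over the cells of each class in embryos with at least 20 such cells, so that the embryo was the replicate. Sums were tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F tests after TMM normalisation and filterByExpr, with Benjamini-Hochberg adjustment over all tested genes at 0.05. The log2 fold change is day 16 minus day 12, and its SE is its size divided by the square root of F. The difference of day effects between trophoblast-like and hypoblast-like cells was tested as the class by day term with an intercept for each embryo, and is positive where the day effect was larger in hypoblast-like cells. Values given for each embryo group are means of TMM-normalised CPM. A fold against a group with no UMI was set against a floor of 3 counts over the group, and 1 to 3 counts were given as a ratio with its 95% counting interval. With 3 embryos of each day in each class test, the depth at days 12 and 16 was 2765827 and 412863 UMIs for trophoblast-like cells. For hypoblast-like cells it was 1493776 and 1830526 UMIs.

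Gene lists, 34 of pathways and 6 of cell type markers, were fixed before the data were examined, as were the comparisons, the rule for named genes and most alternatives. Lists with at least 5 tested members were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2, an inter-gene correlation preset at 0.01, and again with it estimated, and by fry. In whole embryos 37 lists had enough members, and 19 passed with the preset and 0 with an estimated correlation. The fry p values were adjusted over the same lists. The level of APOA1 that free RNA would give was computed after the data were seen, from the share of the other hypoblast markers. In trophoblast-like cells 11 of 32 lists passed with the preset and 0 with an estimated correlation, and in hypoblast-like cells 19 of 33 and 0. The mesoderm, cumulus and blood, immune and endothelial marker lists had under 5 tested members in all 3. Named genes were the 12 largest rises and 12 largest falls in whole embryos, 6 each way in each class and 4 each way for the difference of classes, among genes with a symbol, at least median abundance, an adjusted p below 0.05 and, but for the difference of classes, no overlap between days. Besides these, up to 4 members of smallest p of each list that passed and a set of lineage genes were named whatever their values.

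Shares of cells, values per embryo and the spread between embryos were compared by exact permutation tests, 2-sided, over 70 arrangements of 4 against 4 embryos (scipy 1.17.1), with Benjamini-Hochberg adjustment over the classes or measures. With 3 against 3 embryos the smallest p is 0.10. The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom with quality weights, no low-count filter, thinning to the smallest total, other cell thresholds (500 or 100 genes, 10% mitochondrial UMIs), clustering at resolution 2 or centred within embryos, all barcodes, equal weight per cell (limma on log2 of mean CPM plus 1), removal of mitochondrial and ribosomal protein genes, and each embryo left out in turn. Doublet removal, planned for the main values where scrublet worked, was made an alternative after the data were seen. Added after the data were seen were cells under or from 1000 genes and embryos with at least 5 cells of a class. So were embryos with at least 60% of UMIs in called cells, and list tests in hypoblast-like cells. Plots were drawn with matplotlib 3.10.9.

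The tests were tested on simulated data made from the observed means and dispersions, with 200 changed genes in each of 10 runs. At a 2-fold and a 4-fold change, 10.3% and 75.9% of genes were recovered in whole embryos, 10% and 66% in trophoblast-like cells, 9.3% and 70.5% in hypoblast-like cells and 1.6% and 21.9% for the difference of classes. False calls made up 4.33%, 6.75%, 7.32% and 4.08% of calls. A list raised 2-fold was called in 10 of 10 runs, and 1 of 359 tests of other lists was. The simulated genes were drawn independently of each other, while estimated correlations in whole embryos reached 0.694 (ribosomal proteins). The rate of false list calls therefore does not carry over to the lists called with the preset correlation.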

Results

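Single cells of 8 cattle embryos produced in vitro were profiled by PIP-seq, a droplet method that tags the mRNA of each cell with a barcode and each molecule with a unique molecular identifier (UMI). Each embryo gave its own library, 4 from embryos collected on day 12 after fertilization and 4 from day 16, so the embryo was the replicate. The libraries of day-12 embryos 1 to 4 held 1774609, 1335957, 600754 and 2199942 UMIs, and those of day-16 embryos 1 to 4 held 3779013, 527319, 663299 and 1319555. Of these UMIs, 74.4%, 80.2%, 81.5% and 81.9% lay in called cells at day 12 and 42.3%, 23.9%, 68.1% and 61.7% at day 16. Called cells held fewer of them at day 16 (79.5% ± 3.44 against 49.0% ± 19.99, SD, n = 4, exact permutation p = 0.0286, 2-sided, chosen after the data were seen). A called cell was a barcode with at least 200 detected genes and at most 20% of its UMIs from mitochondrially encoded genes. Genes are named by the symbols deposited with the counts; genome build and gene positions were not given, and PPARG and XIST had no symbol there, so any counts of theirs could not be identified. Intervals and floors given for low counts cover counting error only.

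The 1466 called cells fell into 14 clusters, which were named from marker genes. Trophoblast, the outer layer that forms the placenta, gave 779 trophoblast-like cells, with PTGS2 at 774 counts per 1000000 UMIs (CPM), IFNT at 404 CPM and GATA2 at 322 CPM over all cells of the class, against 5.53, 3.42 and 10.005 CPM in hypoblast-like cells. KRT8 told the classes apart less, at 5668 CPM against 4391 CPM in hypoblast-like and 3007 CPM in unnamed cells. Hypoblast, the layer that lines the yolk sac, gave hypoblast-like cells with APOA1 at 16064 CPM, against 212 CPM in trophoblast-like cells, and FN1 at 5053 CPM, against 23.6 CPM. An APOA1 UMI was present in 94.2% of hypoblast-like and 26.3% of trophoblast-like cells, whose median depths were 904 and 614 UMIs. The second share may be background for APOA1, and it sets no limit for other genes. Epiblast, the source of the embryo proper, gave 14 epiblast-like cells with POU5F1 at 1055 CPM, NANOG at 339 CPM and SOX2 at 238 CPM. These had a median of 17024.5 UMIs. With predicted doublets removed and cells clustered again, no cluster had NANOG or POU5F1 among its 10 genes of highest fold. The epiblast name then went to 48 cells with a median of 469 UMIs, led by ARAP2, RIF1 and CPNE3, so the class was not kept there. The unnamed clusters numbered 2, one of 111 cells and one of 199 cells, of which 98.5% came from day-16 embryo 1. The 5 largest barcodes held 21.1% to 68.3% of the UMIs of an embryo's called cells. Whether such barcodes, with up to 189446 UMIs, were single cells or clumps of cells was not tested, so class sums and shares of UMIs are those of barcodes.

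Over all classes together, called cells of day-16 embryos were shallower than those of day-12 embryos. Day-12 embryos gave 176, 169, 58 and 163 called cells and day-16 embryos 541, 58, 62 and 239 (141.5 ± 55.9 against 225 ± 227, SD, n = 4, exact permutation, adjusted p = 0.686). The median UMIs per cell were 813 ± 145 at day 12 and 570 ± 47.6 at day 16, and the median detected genes were 541 ± 74.0 and 376 ± 36.0 (SD, n = 4, exact permutation, adjusted p = 0.0381 for each). The mitochondrially encoded share of UMIs was 1.91% ± 0.342 at day 12 and 1.13% ± 0.140 at day 16 (SD, n = 4, exact permutation, adjusted p = 0.0381). The lower depth did not hold in hypoblast-like cells, whose median UMIs in embryos 1 to 4 were 793, 446.5, 797 and 970 at day 12 and 550, 1182, 18176 and 1227 at day 16. These were 2-sided tests over 70 arrangements of the embryos, whose smallest p is 0.0286. The medians rested on the cell threshold, since with at least 500 genes per cell the difference in median UMIs was -901 (adjusted p = 0.152, exact permutation). With at least 100 genes it was -49.0, and with predicted doublets removed, as planned where scrublet worked, -26.2 (adjusted p over all alternatives 0.0381 to 0.8286).

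The first comparison asked whether the makeup of the embryo differed between days. Of the UMIs of called cells, hypoblast-like cells held 81.6% ± 12.2 at day 16 and 35.6% ± 20.3 at day 12, and trophoblast-like cells 11.6% ± 4.44 and 57.6% ± 28.0 (SD, n = 4, exact permutation, adjusted p = 0.0381 for each, chosen after the data were seen). These shares describe called cells and not the embryo, since at day 16 55.8% of trophoblast marker UMIs and 31.6% of hypoblast marker UMIs lay outside called cells. The trophoblast marker sum includes KRT8 and KRT18, which were also high in hypoblast-like cells, so it does not measure trophoblast RNA alone. By number of cells, hypoblast-like cells made up 28.7% ± 23.2 at day 12 and 33.3% ± 16.2 at day 16, and trophoblast-like cells 66.7% ± 25.0 and 41.8% ± 12.1 (SD, n = 4, exact permutation, adjusted p = 0.771 and 0.286). Epiblast-like cells made up 1.90% ± 2.32 at day 12 and 0.323% ± 0.647 at day 16 (SD, n = 4, exact permutation, adjusted p = 0.343). They were found in day-12 embryos 1, 3 and 4 and day-16 embryo 1. The other 3 day-16 embryos gave 0 of 359 cells, which allows a share of up to 0.836%. Cells of the unnamed clusters made up 2.76% ± 1.59 and 24.6% ± 14.4 (SD, n = 4, exact permutation, p = 0.0286, adjusted p = 0.114). The direction for hypoblast-like cells turned to -3.41 points without day-12 embryo 2 and to -2.15 points without day-16 embryo 2. For epiblast-like cells the difference of -1.57 points ran from -2.20 to -0.479 with 1 embryo left out.

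**Figure D1:**
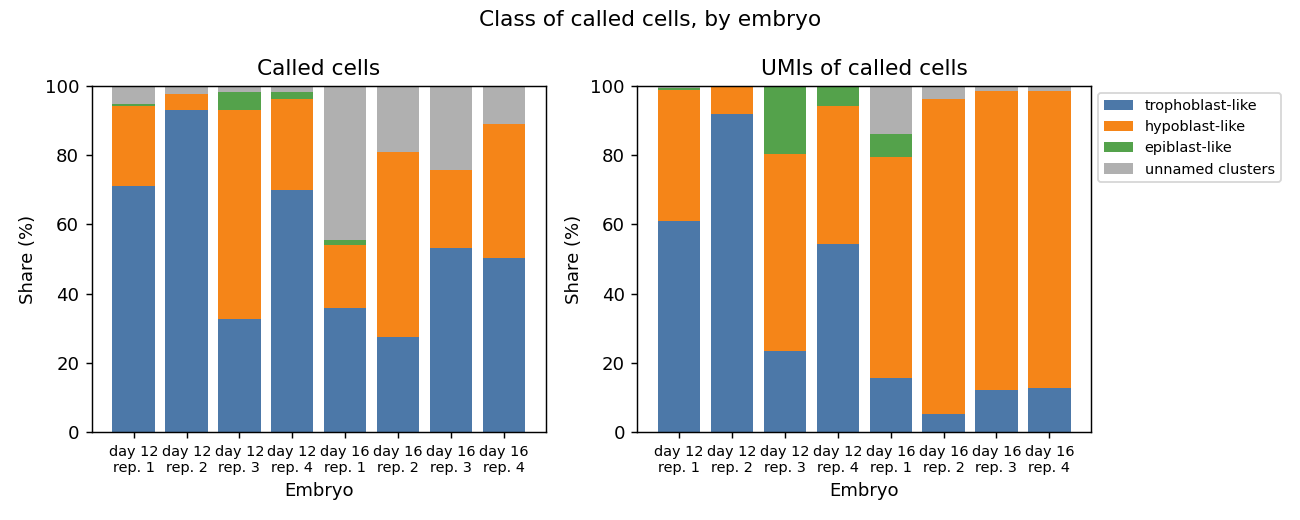
Stacked bars give the share of called cells (left) and of their UMIs (right) in each class, in percent, for each of the 8 embryos. Hypoblast-like cells hold most of the UMIs in every day-16 embryo (mean 81.6%), while the trophoblast-like and hypoblast-like shares of cells overlap between days and the unnamed shares do not.

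The second comparison asked which genes differed between days in the embryo taken as a whole. Between day 12 and day 16 the embryos came to express some growth-factor and liver-type secreted genes that were almost absent before. IGF2 (ENSBTAG00000013066), an imprinted fetal growth factor, rose from 4.50 ± 1.58 to 1455 ± 499 normalised CPM (SD, n = 4, log2 fold change 8.21, SE 0.44, adjusted p = 7.6e-07). IGFBP1 (ENSBTAG00000046768), which binds insulin-like growth factors, had no UMI in the day-12 cells and 286 ± 119 CPM at day 16 (SD, n = 4), at least 306-fold higher against a floor of 3 counts over the group (adjusted p = 1.3e-05). SERPINA1, a protease inhibitor secreted by liver and yolk sac, rose from 0.791 ± 1.58 to 419 ± 215 CPM, and ADM, the vasodilator adrenomedullin, from 3.26 ± 0.874 to 287 ± 61.0 CPM (SD, n = 4, adjusted p = 1.4e-05 and 7.0e-07). The largest fall was in FAM151A, from 379 ± 281 to 2.43 ± 4.86 CPM (SD, n = 4, log2 fold change -7.20, SE 0.91, adjusted p = 0.00026).

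The other large rises were in FCGR1A (log2 fold change 7.96), an immunoglobulin receptor, DUSP9 (7.73), a MAP kinase phosphatase, CD44 (7.50), a hyaluronan receptor, APOH (7.11), MYL3 (6.49), a myosin light chain, IGFBP7 (6.27) and COLEC12 (5.52). TF, which encodes transferrin, had 2 UMIs at day 12 and 281 at day 16, a ratio of 220 with a 95% counting interval of 60.3 to 1825. The other large falls were in BCS1L (-3.40), an assembly factor of respiratory complex III, the transporters SLC30A2 (-3.36), SLC9A3 (-2.69) and SLC34A2 (-2.68), DNMT3B (-3.11), a DNA methyltransferase, GCA (-2.86), IDE (-2.79), IGFBP3 (-2.74), CDIP1 (-2.74), PLLP (-2.70) and MAD1L1 (-2.68). For all of these the 4 embryos of one day lay apart from the 4 of the other, with adjusted p from 6.0e-06 to 0.019.

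Lineage genes were compared over the whole embryo, where the share of hypoblast-like UMIs was 46.0 points higher at day 16. Of 8 endoderm transcription factors tested, 4 rose and 4 did not pass (adjusted p = 0.0021, adjusted p = 0.33 with an estimated correlation), among them HNF4A from 58.5 ± 32.0 to 234 ± 44.4 CPM and GATA4 from 32.8 ± 16.2 to 119 ± 25.8 CPM (SD, n = 4). NR5A2 (2.65) and FOXA1 (2.81) were the others, and 6 members rose adjusted over the list alone. Of 14 trophoblast transcription factors, 5 fell (adjusted p = 0.016, adjusted p = 0.47 with an estimated correlation), 7 adjusted over the list alone. They included CDX2 (-2.02), GATA2 (-1.66), TFAP2C (-2.34) and VGLL1 (-1.84). VGLL1 turned to 0.28 with equal weight per cell, a setting that also replaced edgeR by limma. TFAP2A also fell (-1.41, adjusted p = 0.023). Of 20 hypoblast markers 12 rose, 14 adjusted over the list alone (adjusted p = 1.7e-07, adjusted p = 0.33 with an estimated correlation). Of 17 trophoblast markers 5 fell, as many adjusted over the list alone (adjusted p = 0.039, adjusted p = 0.54 with an estimated correlation). APOA1 rose from 2740 ± 1483 to 25898 ± 16949 CPM (SD, n = 4, log2 fold change 3.24, adjusted p = 0.0022). GATA3 (-0.31), GATA6 (0.24), FOXA2 (1.32), SOX17 (1.197), PTGS2 (-0.97) and POU5F1 (-1.30) did not pass (adjusted p from 0.10 to 0.71). Each of these turned direction under at least 1 alternative, such as GATA3 to 1.44 and PTGS2 to 0.89 over all barcodes. With 1 embryo left out, POU5F1 ran from -4.13, which passed without day-16 embryo 1, to -0.54, SOX17 from 0.36 to 2.01 and PTGS2 from -1.22 to -0.37. TBXT and EOMES, genes of gastrulation, had 5 and 5 UMIs at day 12 and 1 and 0 at day 16, and AFP had 1 and 4. NANOG had 95 and 15 and SOX2 70 and 25, at day 16 each in 1 embryo alone. None of these passed the low-count filter, so none was tested.

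Of 13 apolipoprotein and liver-type secreted genes 11 rose, and 11 did adjusted over the list alone (adjusted p = 4.5e-11, adjusted p = 0.088 with an estimated correlation), among them AHSG, a serum glycoprotein, from 81.8 ± 46.5 to 2970 ± 890 CPM (SD, n = 4). APOB had 1 UMI at day 12 and 222 at day 16, a ratio of 348 with a 95% counting interval of 61.7 to 13787. Of 20 matrix and basement membrane genes 12 rose, 13 adjusted over the list alone (adjusted p = 4.3e-07, adjusted p = 0.33 with an estimated correlation). They included FN1, fibronectin, from 580 ± 292 to 8276 ± 4504 CPM, and SPARC from 279 ± 145 to 1993 ± 506 CPM (SD, n = 4), besides HSPG2 (3.87) and COL4A1 (2.62). Of 21 BMP, nodal and TGF-beta genes 8 rose, 10 adjusted over the list alone (adjusted p = 8.3e-05, adjusted p = 0.33 with an estimated correlation). Among these were BMP4 from 9.14 ± 4.55 to 173 ± 9.56 CPM (SD, n = 4), SMAD6 (2.91), TGFB1 (3.13) and BMP7 (1.88). Of 15 FGF, IGF and EGF genes 6 rose and 2 fell, 7 and 3 adjusted over the list alone (adjusted p = 0.036, adjusted p = 0.33 with an estimated correlation), with IGFBP2 (3.54) and IGFBP4 (4.28) next to IGF2 and IGFBP7. Of 11 imprinted genes 5 rose, 7 with 2 falls adjusted over the list alone (adjusted p = 0.0010, adjusted p = 0.088 with an estimated correlation). Those that rose included CDKN1C (4.82), a growth inhibitor, GNAS (0.93, 1 of several features of that symbol) and IGF2R (0.93). With equal weight per cell and limma in place of edgeR, IGF2R turned to -0.31. Of the gastrulation and mesoderm list 5 of 23 members could be tested and 4 rose, 5 adjusted over the list alone (adjusted p = 0.00038, adjusted p = 0.088 with an estimated correlation). These were the ligand BMP4, SNAI1 (1.68), a repressor of epithelial genes, CDH2 (1.97), which encodes N-cadherin, and VIM (1.96), which encodes an intermediate filament. Hypoblast markers rose alongside. Within hypoblast-like cells BMP4 also rose, while SNAI1 and CDH2 did not pass (adjusted p = 0.055 and 0.052), which does not show that they were unchanged there.

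Of 17 hypoxia genes 10 rose, also adjusted over the list alone (adjusted p = 8.3e-07, adjusted p = 0.088 with an estimated correlation). Such genes were NDRG1 from 107 ± 17.1 to 1833 ± 365 CPM (SD, n = 4), MXI1 (5.38), EGLN3 (3.68) and ADM. Of 20 glycolysis genes 7 rose, 9 adjusted over the list alone (adjusted p = 0.00069, adjusted p = 0.33 with an estimated correlation). They encode, among others, the glucose transporters SLC2A3 (2.57) and SLC2A1 (2.32), the lactate transporter SLC16A3 (2.60) and PGK1 (1.28). Of 19 immediate early genes 10 rose, 12 adjusted over the list alone (adjusted p = 2.3e-05, adjusted p = 0.33 with an estimated correlation), such as EGR1 (2.76), DUSP1 (2.26), JUN (2.18) and FOS (2.13), which also respond to handling of cells. Of 29 G2 and M phase genes 10 fell, 11 adjusted over the list alone (adjusted p = 5.3e-05, adjusted p = 0.34 with an estimated correlation), with MKI67 from 57.7 ± 9.96 to 12.0 ± 8.91 CPM (SD, n = 4), ANLN (-2.51), HMGB2 (-1.56) and CENPE (-1.64). Of 24 S phase genes 11 fell, 12 with 1 rise adjusted over the list alone (adjusted p = 0.0010, adjusted p = 0.33 with an estimated correlation), with RRM2 (-2.06), MCM4 (-1.39), CCNE1 (-1.82) and FEN1 (-1.61).

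Of 30 nuclear oxidative phosphorylation genes 4 fell, also adjusted over the list alone (adjusted p = 0.0014, adjusted p = 0.57 with an estimated correlation), ATP5MC1 (-1.97), UQCRC1 (-1.54), NDUFV1 (-1.10) and SDHA (-1.04). Of 13 mitochondrially encoded genes 1 fell, MT-CO2 (-0.89), and none did adjusted over the list alone (adjusted p = 0.021, adjusted p = 0.36 with an estimated correlation, values -1.12 for MT-ATP8, -0.85 for ND5 and -0.61 for MT-ND4). Of 23 translation and nucleolus genes 7 fell and 1 rose, 8 and 1 adjusted over the list alone (adjusted p = 0.031, adjusted p = 0.38 with an estimated correlation), with POLR1A (-1.27), NOP56 (-1.05), DKC1 (-0.97) and EIF5A (-0.90). Of 34 ribosomal protein genes 4 rose, RPL18 (1.01), RPLP0 (0.93), RPS25 (0.87) and RPL37 (0.86), and none did adjusted over the list alone (adjusted p = 0.0024, adjusted p = 0.59 with an estimated correlation). Among the lists that did not pass were integrins and actin motility, with 7 of 23 rising (adjusted p = 0.052), epiblast markers, with 2 of 6 falling (adjusted p = 0.056), pluripotency (adjusted p = 0.097), interferon response (adjusted p = 0.52) and conceptus secreted proteins, of which none of 8 passed (adjusted p = 0.61). By fry, which asks whether the members of a list move on balance one way and makes no comparison with other genes, the nuclear oxidative phosphorylation, ribosomal protein, trophoblast factor and trophoblast marker lists did not pass, while the other called lists did.

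Of 9727 genes tested in the whole embryo, 1265 rose and 914 fell, and the embryos of the days did not overlap for 1249 genes higher and 1235 lower at day 16 (25.5%, against 2.86% by chance). The count of 2179 fell to 648 when every embryo was thinned to the smallest total and to 1346 without day-12 embryo 4. It was 275 with equal weight per cell, but that setting also replaced edgeR by limma. The lower count there cannot be put down to the weighting alone. Without predicted doublets, whose removal had been planned where scrublet worked, the count was 1352. In settings chosen after the data were seen, cells under 1000 genes alone gave 125, and embryos with at least 60% of UMIs in called cells gave 1870.

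**Figure D2:**
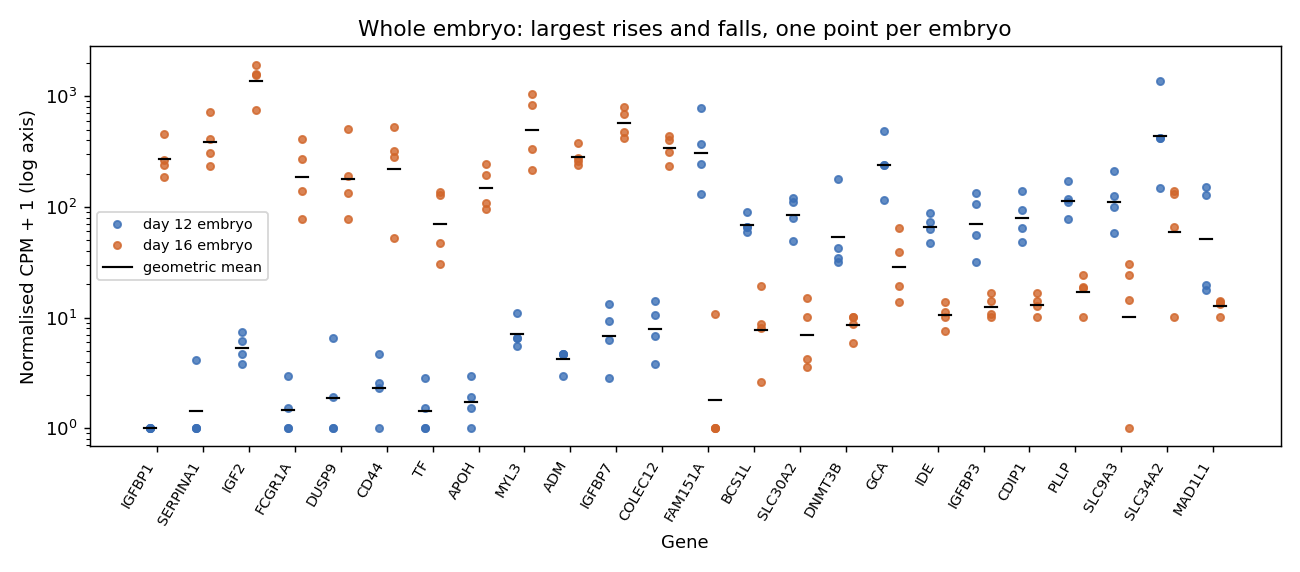
Each point is 1 embryo's normalised CPM plus 1 (log axis) for the 12 largest rises and 12 largest falls in the whole embryo, with day 12 in blue, day 16 in orange and the geometric mean of each day as a bar. The points of the 2 days do not overlap for any of these genes.

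The third comparison asked how trophoblast-like cells differed between days, in day-12 embryos 1, 2 and 4 and day-16 embryos 1, 3 and 4, which had at least 20 such cells. Of the day-12 class's UMIs 81.5% came from a cluster of 56 cells with no day-16 cell, and of the day-16 class's 44.9% and 25.5% came from 2 other clusters, so the days compare largely different clusters. IFNT (ENSBTAG00000048549), a gene of interferon tau, the signal by which a ruminant conceptus maintains pregnancy, rose from 272 ± 139 to 1135 ± 440 CPM, and IFNT2 (ENSBTAG00000072970) from 55.8 ± 14.0 to 379 ± 311 CPM (SD, n = 3, log2 fold change 2.07, SE 0.38, and 2.89, SE 0.44, adjusted p = 0.0021 and 0.00061). PAG2, a pregnancy-associated glycoprotein, rose from 145 ± 68.2 to 1899 ± 262 CPM, and PTGS2, the enzyme that starts prostaglandin synthesis, from 624 ± 268 to 1611 ± 267 CPM (SD, n = 3, adjusted p = 4.7e-05 and 0.0094). CDX2, a trophoblast transcription factor of early development, fell from 82.8 ± 11.9 to 17.9 ± 6.94 CPM (SD, n = 3, log2 fold change -2.41, SE 0.52, adjusted p = 0.0066). Its day-16 value rests on few counts, since trophoblast-like cells of all embryos held 252 CDX2 UMIs at day 12 and 5 at day 16. The tested day-16 sums held 412863 UMIs and the day-12 sums 2765827.

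The largest rises were in IGFL1 from 1.35 ± 1.49 to 237 ± 237 CPM (SD, n = 3, log2 fold change 7.46, SE 0.75, adjusted p = 6.6e-05), the calcium-binding S100G (5.53) and S100A1 (4.68), CDKN1C (4.99), NDRG1 (4.27) and the transcription factor NFATC1 (4.08). The largest falls were in FAM151A (-5.08), ARRDC1 (-3.73) and DNMT3A, a DNA methyltransferase, from 367 ± 182 to 38.3 ± 19.01 CPM (SD, n = 3, log2 fold change -3.53, adjusted p = 0.00074). At day 16 SDC1 had 1 UMI (ratio 0.0277, counting interval 0.000698 to 0.156), BCS1L had 2 (0.0598, 0.0072 to 0.219) and NUDCD3 had 2 (0.0632, 0.0076 to 0.231). APOA1, a hypoblast marker, was higher at day 16 (2.30, adjusted p = 0.016), at 674 ± 230 CPM against 141 ± 149 (SD, n = 3). Free RNA of hypoblast-like cells, at the share of the other hypoblast markers, would give 146 to 194 CPM at day 12 and 290 to 591 CPM at day 16. Before scaling, 42.3 to 321 CPM and 429 to 709 CPM were measured, so its rise was not separated from background. GATA3 (0.98), TFAP2A (0.75) and GATA2 (0.14, but -0.26 to -0.09 under 7 alternatives) did not pass (adjusted p = 0.059, 0.17 and 0.80). The IFNT and PAG genes have close paralogs, and how reads shared among them were counted is not known.

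Of 8 conceptus secreted genes 6 rose, 7 adjusted over the list alone (adjusted p = 3.7e-05, adjusted p = 0.28 with an estimated correlation), SSLP1 (1.56) among them. Of 9 prostaglandin and PPAR genes 5 rose, 6 adjusted over the list alone (adjusted p = 0.011, adjusted p = 0.32 with an estimated correlation), including the prostaglandin carrier SLCO2A1 (2.67), AKR1B1 (1.35) and the PPAR partner RXRA (1.85). Of 17 trophoblast markers 6 rose and 2 fell, 8 and 2 adjusted over the list alone (adjusted p = 0.011, adjusted p = 0.31 with an estimated correlation). Of 34 ribosomal protein genes 20 rose, 27 adjusted over the list alone (adjusted p = 9.8e-13, adjusted p = 0.31 with an estimated correlation), such as RPLP0 from 2966 ± 462 to 8397 ± 953 CPM (SD, n = 3), RPS25 (1.501), RPL18 (1.40) and RPL23 (1.34). Of 13 mitochondrially encoded genes 7 fell, 10 with 1 rise adjusted over the list alone (adjusted p = 0.00042, adjusted p = 0.32 with an estimated correlation), such as COX1 (-1.99), MT-CO2 (-1.70), MT-ND4 (-1.64) and MT-CYB (-1.53). Of 27 G2 and M phase genes 6 fell, 13 adjusted over the list alone (adjusted p = 8.1e-05, adjusted p = 0.31 with an estimated correlation), including KIF23 (-2.14) and TACC3 (-1.72). MKI67 had 2 UMIs at day 16 (ratio 0.0893, counting interval 0.0107 to 0.328) and NDC80 had 1 (0.0677, 0.0017 to 0.386).

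Of 19 glycolysis genes 8 rose, also adjusted over the list alone (adjusted p = 4.6e-05, adjusted p = 0.28 with an estimated correlation), with SLC16A3 (2.72), SLC2A3 (1.59), SLC2A1 (1.56) and GAPDH (1.35). Of 14 hypoxia genes 6 rose, 8 adjusted over the list alone (adjusted p = 0.00042, adjusted p = 0.28 with an estimated correlation), with NDRG1 from 45.0 ± 20.3 to 871 ± 57.0 CPM (SD, n = 3), PGK1 (1.22) and ERO1A (1.28). Of 16 immediate early genes 5 rose, 7 adjusted over the list alone (adjusted p = 7.7e-06, adjusted p = 0.28 with an estimated correlation), with EGR1 (3.10), FOS (2.75), JUN (2.59) and IER3 (2.06). Of 11 WNT genes 3 rose, 6 adjusted over the list alone (adjusted p = 0.0092, adjusted p = 0.28 with an estimated correlation), WNT4 (2.61), WNT5B (2.66) and TCF7L1 (1.05), while CTNNB1 was at 0.77. Of 9 BMP, nodal and TGF-beta genes 3 rose, also adjusted over the list alone (adjusted p = 0.026, adjusted p = 0.28 with an estimated correlation), TGFB1 (2.86), SMAD2 (1.54) and ID2 (1.77), while SMAD4 was at 0.68. Heat shock and unfolded protein genes did not pass as a list, with 7 of 26 falling (adjusted p = 0.11), nor did oxidative stress genes, with 3 rising and 2 falling of 19 (adjusted p = 0.49). By fry the prostaglandin and trophoblast marker lists did not pass in this class (adjusted p = 0.053 and 0.064), while the other called lists did.

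Of 7521 genes tested in trophoblast-like cells, 662 rose and 318 fell, and 34.8% did not overlap between days (10% by chance). The count of 980 fell to 263 when thinned, to 536 without day-12 embryo 4 and to 514 without day-16 embryo 1. It was 569 with clustering centred within embryos and 1637 without a low-count filter, of which 675 rose and 962 fell. In cells under 1000 genes alone, a choice made after the data were seen, 19 genes rose and 42 fell. With at least 100 genes per cell, which allowed 4 embryos of each day, 441 rose and 755 fell. More genes rose than fell under every other alternative, so the balance of rises and falls is not settled.

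**Figure D3:**
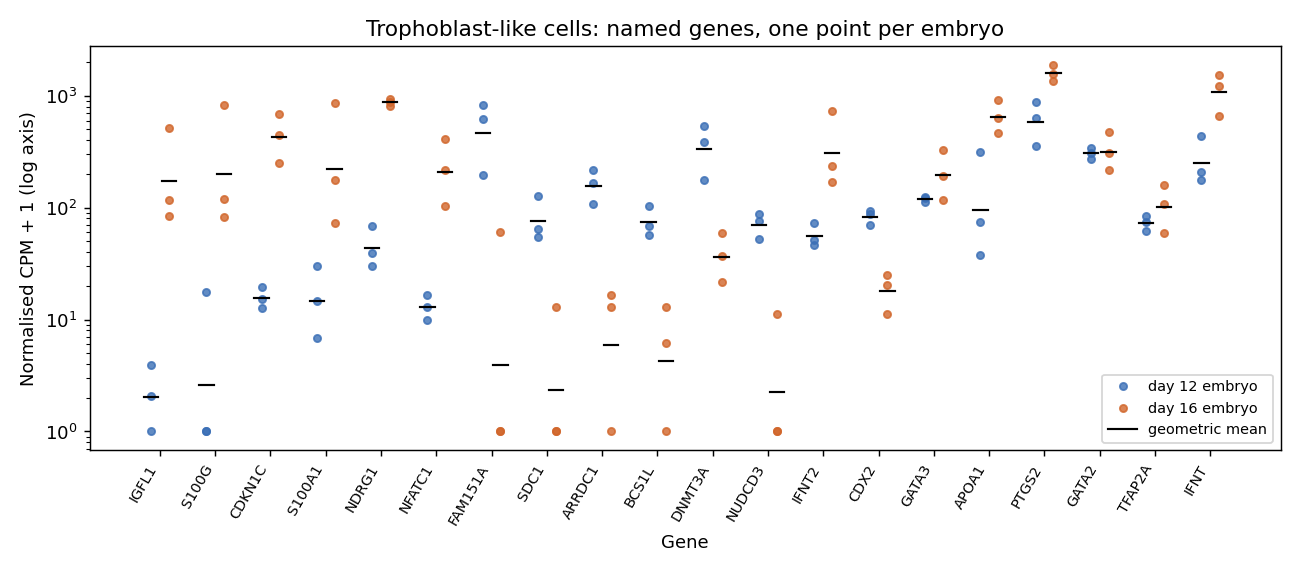
Each point is 1 embryo's normalised CPM plus 1 (log axis) in trophoblast-like cells for the 6 largest rises, the 6 largest falls and the genes named in any case, with day 12 in blue, day 16 in orange and the geometric mean of each day as a bar. IFNT, IFNT2 and PTGS2 lie higher at day 16 (means 1135, 379 and 1611 CPM) and CDX2 lower (17.9 CPM, on 5 or fewer UMIs).

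The fourth comparison asked how hypoblast-like cells differed between days, in day-12 embryos 1, 3 and 4 and day-16 embryos 1, 2 and 4. Over all 8 embryos, of the day-12 class's UMIs 92.5% came from a cluster of 24 day-12 cells and 1 day-16 cell, and of the day-16 class's 90.5% from one of 69 cells with no day-12 cell. The days thus compare largely different clusters. MT1E (ENSBTAG00000001595, 1 of 2 features with that symbol), a metal-binding protein, had no UMI at day 12 and 793 ± 193 CPM at day 16 (SD, n = 3), at least 393-fold higher (adjusted p = 3.4e-06). IGF2 rose from 9.56 ± 2.23 to 1700 ± 582 CPM (SD, n = 3, log2 fold change 7.37, SE 0.48, adjusted p = 2.0e-06). POU5F1, the pluripotency factor, fell from 114 ± 16.3 to 12.1 ± 13.5 CPM (SD, n = 3, log2 fold change -2.68, SE 0.46, adjusted p = 0.0014). The tested day-12 sums held 1493776 UMIs and the day-16 sums 1830526.

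IGFBP1, MT1A and APOB also had no UMI at day 12 and were at least 130-fold, 83.0-fold and 57.4-fold higher at day 16, and DUSP9 had 1 UMI and then 366 (ratio 299, counting interval 53.3 to 11829). The largest falls were in B3GNT6 (-4.77), RSPO3, a WNT co-activator, from 183 ± 20.5 to 5.23 ± 7.47 CPM (SD, n = 3, log2 fold change -4.42, adjusted p = 7.9e-05), DNMT3B (-3.98), the lipid transporter SPNS2 (-3.94), IYD (-3.72) and AGPAT4 (-3.66). APOA1 rose from 7617 ± 946 to 35372 ± 18429 CPM (SD, n = 3, log2 fold change 2.21, SE 0.58, adjusted p = 0.016). GATA4 (0.56), FOXA2 (0.08), SOX17 (-0.30) and GATA6 (-0.92) did not pass (adjusted p = 0.22, 0.92, 0.84 and 0.073). With 1 embryo left out, SOX17 ran from -3.85 to 0.53 and FOXA2 from -0.33 to 0.44. With limma-voom SOX17 (-2.60) and GATA6 (-1.006) passed.

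Lists were tested in this class as a result added after the data were seen, with the same members. Of 13 apolipoprotein and liver-type secreted genes 10 rose, also adjusted over the list alone (adjusted p = 2.2e-07, adjusted p = 0.16 with an estimated correlation), including SERPINA1 (7.19), APOH (5.81) and AHSG (4.17). Of 19 hypoblast markers 10 rose and 1 fell, 11 and 2 adjusted over the list alone (adjusted p = 0.0072, adjusted p = 0.49 with an estimated correlation). Of 20 matrix genes 9 rose and 1 fell, 10 and 2 adjusted over the list alone (adjusted p = 0.035, adjusted p = 0.61 with an estimated correlation). Matrix genes with rises were FN1 from 1667 ± 297 to 10633 ± 5566 CPM (SD, n = 3), HSPG2 (3.24), NID2 (1.65) and SPARC (1.63). Of 10 imprinted genes 5 rose, 6 adjusted over the list alone (adjusted p = 0.00063, adjusted p = 0.17 with an estimated correlation), with CDKN1C (5.01), PEG3 (2.73) and NNAT (1.90) next to IGF2. Of 11 FGF, IGF and EGF genes 5 rose and 2 fell, 7 and 2 adjusted over the list alone (adjusted p = 0.0046, adjusted p = 0.19 with an estimated correlation), among them IGFBP7 (5.72), IGFBP2 (3.99) and IGFBP4 (3.34). Of 20 BMP, nodal and TGF-beta genes 7 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.013, adjusted p = 0.19 with an estimated correlation), with BMP4 (4.21), ID1 (2.89) and SMAD6 (2.13). TGFB1 had no UMI at day 12 and was at least 20.7-fold higher.

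Of 9 pluripotency genes 4 fell, also adjusted over the list alone (adjusted p = 0.016, adjusted p = 0.19 with an estimated correlation), with ZFP42 (-2.41), DPPA4 (-1.77) and DPPA3, which had 27 UMIs at day 12 and 0 at day 16, at least 11.03-fold lower. Of 5 epiblast markers 3 fell, also adjusted over the list alone (adjusted p = 0.013, adjusted p = 0.19 with an estimated correlation). Of 29 G2 and M phase genes 12 fell, 15 adjusted over the list alone (adjusted p = 6.3e-06, adjusted p = 0.19 with an estimated correlation), with HMGB2 (-2.26), MKI67 (-2.47), ANLN (-3.11) and CCNA2 (-2.16). Of 23 S phase genes 12 fell and 1 rose, 14 and 1 adjusted over the list alone (adjusted p = 0.00012, adjusted p = 0.16 with an estimated correlation), with MCM4 (-1.89), MCM3 (-2.29), RRM2 (-2.30) and FEN1 (-2.16). Of 23 translation and nucleolus genes 7 fell, 8 adjusted over the list alone (adjusted p = 0.016, adjusted p = 0.49 with an estimated correlation), EIF5A (-1.16) and EIF4EBP1 (-1.51) among them.

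Of 30 nuclear oxidative phosphorylation genes 15 fell, 16 adjusted over the list alone (adjusted p = 1.2e-06, adjusted p = 0.49 with an estimated correlation), with ATP5MC1 (-2.94), UQCRC1 (-2.19), SDHA (-1.61) and UQCRB (-1.53). Of 13 mitochondrially encoded genes 4 fell, also adjusted over the list alone (adjusted p = 0.013, adjusted p = 0.49 with an estimated correlation), MT-ND4L (-2.19), MT-ATP8 (-1.75), ND5 (-1.38) and MT-CO2 (-1.09). Of 22 cholesterol synthesis genes 4 fell, also adjusted over the list alone (adjusted p = 0.025, adjusted p = 0.66 with an estimated correlation), NSDHL (-2.01), EBP (-1.52), DHCR24 (-1.48) and FDPS (-1.35). Of 20 fatty acid genes 3 fell, also adjusted over the list alone (adjusted p = 0.022, adjusted p = 0.37 with an estimated correlation), FABP5 (-2.93), ACACA (-1.496) and FADS1 (-1.26), with PLIN2 at -0.98. Of 16 hypoxia genes 9 rose and 1 fell, 10 and 1 adjusted over the list alone (adjusted p = 0.00012, adjusted p = 0.19 with an estimated correlation), with ADM (6.73), MXI1 (5.86), EGLN3 (3.46) and NDRG1 (3.22). Of 19 glycolysis genes 6 rose and 2 fell, 7 and 2 adjusted over the list alone (adjusted p = 0.014, adjusted p = 0.59 with an estimated correlation), with SLC2A3 (1.81), SLC2A1 (1.55), PGK1 (1.36) and SLC16A3, whose UMIs went from 2 to 230 (ratio 93.8, counting interval 25.7 to 780). Of 19 immediate early genes 10 rose, 11 adjusted over the list alone (adjusted p = 0.00094, adjusted p = 0.56 with an estimated correlation), with EGR1 (3.17), JUND (1.97), DUSP1 (1.94) and CCN2 (1.91). Of 15 p53 and apoptosis genes 3 rose, 4 adjusted over the list alone (adjusted p = 0.040, adjusted p = 0.24 with an estimated correlation), GADD45A (2.32), SESN1 (1.82) and BBC3 (1.62), with GADD45B at 1.65. By fry, 6 of the 19 called lists did not pass in this class, which were immediate early genes (adjusted p = 0.13), cholesterol synthesis (0.23), mitochondrially encoded genes (0.079), glycolysis (0.058), matrix genes (0.058) and nuclear oxidative phosphorylation (0.0504).

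Of 8203 genes tested in hypoblast-like cells, 946 rose and 754 fell, and 39.0% did not overlap between days (10% by chance). The count of 1700 fell to 673 when thinned and to 857 without day-12 embryo 4. Without predicted doublets, whose removal had been planned where scrublet worked, the count was 305 (237 rises and 68 falls). Cells under 1000 genes alone, a choice made after the data were seen, gave 38 (28 and 10).

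**Figure D4:**
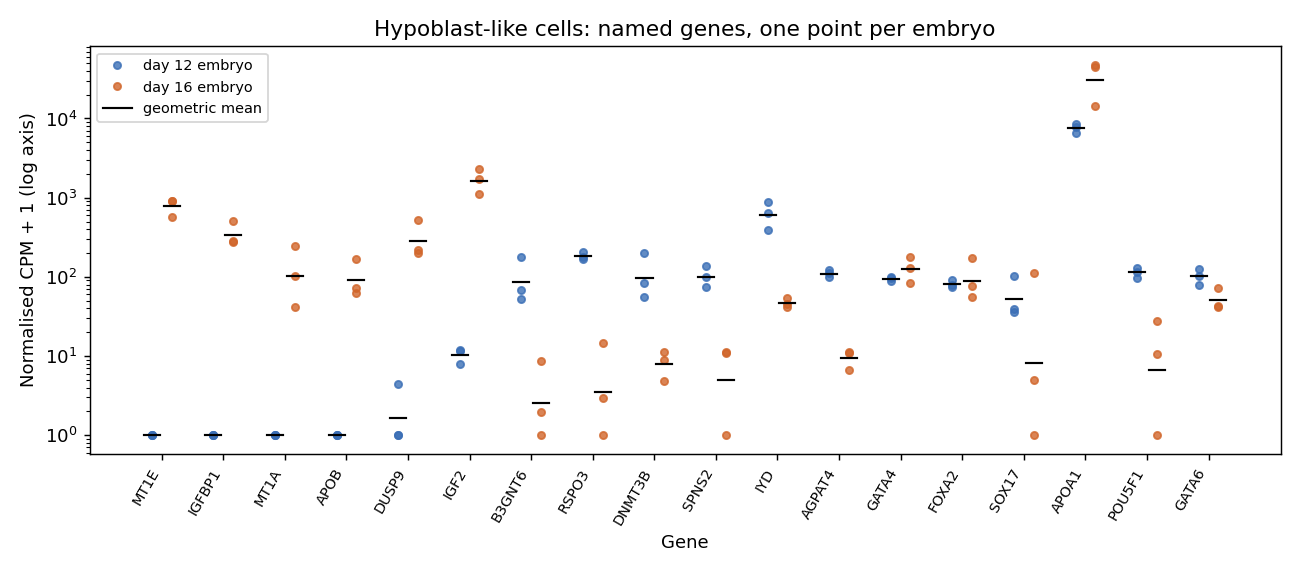
Each point is 1 embryo's normalised CPM plus 1 (log axis) in hypoblast-like cells for the 6 largest rises, the 6 largest falls and the genes named in any case, with day 12 in blue, day 16 in orange and the geometric mean of each day as a bar. IGF2 lies at 1700 CPM on average at day 16 against 9.56 at day 12, while POU5F1 lies at 12.1 against 114.

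No test of epiblast-like cells was possible, since no embryo had 20 of them. The fifth comparison asked which genes responded to day differently in the 2 larger classes, within day-12 embryos 1 and 4 and day-16 embryos 1 and 4. FLT1, a VEGF receptor, rose in hypoblast-like cells (5.35) and did not pass in trophoblast-like cells (0.20), and the day effects differed by 4.53 (SE 0.64, adjusted p = 0.00094). TGM1, a transglutaminase, gave 4.47 and 0.27, a difference of 4.47 (SE 0.68, adjusted p = 0.0016). RBP1, a retinol carrier, rose in trophoblast-like cells (3.92) and fell in hypoblast-like cells (-2.28), a difference of -5.89 (SE 0.74, adjusted p = 0.00025). From day 12 to day 16 FLT1 went from 11 to 371 UMIs in hypoblast-like and from 76 to 13 in trophoblast-like cells. RBP1 went from 90 to 20 and from 20 to 31, and TGM1 from 68 to 1594 and from 316 to 36. FLT1 and RBP1 thus also rest on low counts. The other named genes had 9 or fewer UMIs on at least 1 day in a class. From day 12 to day 16 MT1E went from 0 to 1387 UMIs in hypoblast-like cells (adjusted p = 0.0077), while C1R, a complement protease, went from 17 to 0 in trophoblast-like cells (adjusted p = 0.013) and AKR1D1 from 0 to 11 (adjusted p = 0.020). With a group at 0, the size of these differences was not measured. SKAP1 (-5.10, adjusted p = 0.0036) rested on 6 and 9 trophoblast-like UMIs and PRR15 (-4.29, adjusted p = 0.038) on 1 and 9. Without day-16 embryo 1 AKR1D1 and SKAP1 turned to 0.82 and 1.31. Of 10444 genes tested, 91 had a larger day effect in hypoblast-like and 103 in trophoblast-like cells. The test rested on 2 embryos of each day. With 1 left out, its day had a single embryo and the spread came from the other day alone, so those counts do not test stability. The count of 194 was 35 without day-12 embryo 4, 65 without day-12 embryo 1, 374 without day-16 embryo 4, 65 with DESeq2 and 337 with no low-count filter or with clustering centred within embryos. It was 382 with embryos of at least 5 cells, chosen after the data were seen. More genes had the larger effect in hypoblast-like than in trophoblast-like cells with no low-count filter (213 and 124), centred clustering (234 and 103) and at least 5 cells (218 and 164). Fewer did with DESeq2 (22 and 43), RLE size factors (86 and 119) and resolution 2 (117 and 138), so the balance is not settled.

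Interferon tau was also summed over its 2 named features, IFNT and IFNT2. In trophoblast-like cells the family stood at 360 ± 189 CPM at day 12 and 1247 ± 546 CPM at day 16 (SD, n = 3, log2 difference 1.80, exact permutation p = 0.10, the smallest that 3 against 3 embryos allow). In whole embryos it stood at 257 ± 95.8 and 156 ± 108 CPM (SD, n = 4, log2 difference -0.89, exact permutation p = 0.20). Over all barcodes, called or not, it stood at 295 ± 155 and 881 ± 622 CPM (SD, n = 4, log2 difference 1.47, exact permutation p = 0.0857). The fitted IFNT change in whole embryos was -0.56 (adjusted p = 0.37) and turned to 1.68 over all barcodes (adjusted p = 0.0371). In cells from 1000 genes alone, a choice made after the data were seen, it was -1.38 (adjusted p = 0.0282). IFNT2 was at 0.55 (adjusted p = 0.39), and at 2.99 over all barcodes (adjusted p = 0.00697).

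The last comparison asked whether embryos of one day resembled each other more on one day than on the other. The mean distance between embryos of a day, 1 minus the Spearman correlation over genes, was 0.114 at day 12 and 0.215 at day 16, a difference of 0.101 (exact permutation p = 0.114, 2-sided). Without day-12 embryo 2 or 3 it was 0.119 or 0.128, each with an exact permutation p of 0.0286. Without any other embryo it was 0.0712 to 0.124 (exact permutation p from 0.229 to 0.343). Thinning to the smallest total gave 0.0649 (exact permutation p = 0.0857). Arrangements that mix the days hold distances between days, which ran from 0.275 to 0.462, inside their groups. These p values therefore do not test a difference in spread alone, and whether the spread differed is not decided.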

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

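Chosen only after the result was seen were the test in shallow cells, the splits of the embryos and the alternatives with at least 5 cells per embryo, and every extreme value below was looked for in the data.

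Among 211 groups of 4 embryos, 16 had an embryo whose gap to the nearest, divided by the range of the group, passed the limit of the Dixon test. Chance gives about 1 in 20 groups. Day-12 embryo 3 had the fewest called cells of its day, 58 against 163 to 176 (gap 0.89). The mitochondrial share was highest in day-12 embryo 4, 2.43% against 1.73% to 1.75% (gap 0.963). Epiblast-like cells were seen at day 16 in embryo 1 alone, 1.29% of its cells (gap 1.0). In day-12 embryo 4 SERPINA1 stood at 3.17 CPM (6 UMIs) and APOB at 0.528 CPM (1 UMI), against 0 in the other embryos of that day (gap 1.0 for each), and its IFNT2 value was lowest, 27.4 CPM against 42.4 to 46.3 (gap 0.831). ADM was lowest in day-12 embryo 1, at 1.95 CPM (3 UMIs) against 3.69 to 3.71 (2 to 7 UMIs, gap 0.992), and FAM151A was seen at day 16 in embryo 4 alone, at 9.73 CPM (6 UMIs, gap 1.0). Where the other embryos have 0, any count gives a gap of 1.0, so those of SERPINA1, APOB and FAM151A, on 1 to 6 UMIs, carry no size. Day-12 embryo 3 was highest for DNMT3B, 178 CPM against 30.5 to 41.2 (gap 0.832), and lowest for CCNE1 (24.1 CPM, gap 0.874), EGR1 (50.03 CPM against 114 to 132, gap 0.851) and POLR1A (35.2 CPM, gap 0.843). Day-16 embryo 2 was lowest for MAD1L1 (1 UMI, 9.15 CPM, gap 0.831) and TFAP2A (0 against 12.9 to 21.9 CPM, 5 to 34 UMIs, gap 0.841), again on few UMIs, and highest for TGFB1 (119 CPM against 36.2 to 43.8, gap 0.842). GATA3 was highest in day-16 embryo 1, 117 CPM against 23.3 to 29.2 (gap 0.862).

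The day effect differed between hypoblast-like and trophoblast-like cells, by a test of the difference in 2 embryos of each day, for FLT1 (4.53), TGM1 (4.47) and RBP1 (-5.89), on the log2 scale. The fitted values of C1R (9.28), MT1E (7.15) and AKR1D1 (-6.23) rest on a group with 0 UMIs and give no size, and those of SKAP1 (-5.10) and PRR15 (-4.29) rest on 1 to 9 trophoblast-like UMIs of a day. Without day-16 embryo 1, AKR1D1 turned to 0.82 and SKAP1 to 1.31.

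A signal outside the comparisons was an unnamed cluster of 199 cells, 98.5% of them from day-16 embryo 1. Its genes of highest fold were RBMS3, NCF2, HS3ST4, STC1 and EHMT2. Its best score, 0.498, was for cumulus markers, none of which was among its 10 genes of highest fold. Of trophoblast markers, GATA3 was at 489 CPM, the highest of all clusters, and SSLP1 at 512 CPM. PTGS2 (115 CPM) and IFNT (38.3 CPM) were below every trophoblast-like cluster. Of 212 day-16 GATA3 UMIs, 87 lay in trophoblast-like, 12 in hypoblast-like and 3 in epiblast-like cells, the rest in unnamed clusters. Day-16 embryo 1 also had the highest GATA3 value of its day. With at least 100 genes per cell, a cluster took the cumulus name with a score of 0.543. No biological explanation was tested.

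The whole-embryo change between days may come from a different makeup of classes, since hypoblast-like cells held 35.6% of called UMIs at day 12 and 81.6% at day 16. Of the 1409 genes called in whole embryos and tested in both classes, 67.4% were called in the same direction in at least 1 class, which a change in the shares of these classes alone would not give. The other changes stay open to it, among them lineage factors such as GATA2, which fell in whole embryos and was at 0.14 in trophoblast-like cells. The real split of the 8 embryos gave 2179 genes and the highest of the other splits 0, so 1 of 35 splits was as large, the smallest share possible. Every other split holds embryos of both days in each group, which lowers its count, so the size of the gap adds nothing. Chance is made unlikely at that share but is not excluded. A change with age within the classes is the biological explanation and stays a hypothesis, since the makeup, the depth of cells and the day go together.

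The rises in trophoblast-like cells may come from free RNA of hypoblast-like cells or from shallower day-16 cells. After subtraction of the hypoblast-like profile of each embryo, at shares of 1.43% to 4.50%, 95.2% of the 662 rises were still called. That argues against free RNA of hypoblast-like cells as the source of most of them, while APOA1 stays open. Free RNA of other cells was not tested. In cells under 1000 genes 90.9% of the 242 rises measured kept their direction, but their median log2 fold change went from 1.51 to 0.49, so depth stays open for part of the size. The real split of the 6 embryos gave 980 genes and the highest other 1, with 1 of 10 splits as large, too few for a share under 0.05. With at least 5 cells per embryo 832 genes were called and 82 in the highest other of 35 splits. Of these splits 1 was as large, the smallest share possible, so chance is made unlikely there but is not excluded. Maturation between days stays open as untested.

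In hypoblast-like cells the real split gave 1700 genes and the highest other 0, with 1 of 10 splits as large, too few for a share under 0.05. With at least 5 cells per embryo 1255 genes were called, 0 in the highest other of 35 splits, and 1 split was as large. That is the smallest share possible, so chance is made unlikely there but is not excluded. For the difference of day effects with at least 5 cells, the real split gave 382 genes and the highest of the other splits 57.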

How the results depend on the processing

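Doublet removal had been planned where scrublet worked and was made an alternative after the data were seen. Chosen after the data were seen were the restrictions to cells under or from 1000 genes and to embryos with at least 5 cells of a class. So were the restriction to embryos with at least 60% of UMIs in called cells, and every list alternative in hypoblast-like cells. Of the values of named genes under all alternatives, 1717 of 1855 for called genes in whole embryos kept direction and call, 136 lost the call and 2 turned. In trophoblast-like cells 821 of 894 kept both and 73 lost the call, in hypoblast-like cells 1309 of 1419 and 110, and for the difference of classes 64 of 78 kept both, 12 lost the call and 2 turned. RLE size factors moved the median log2 fold change by -0.03, -0.03 and -0.02 in whole embryos, trophoblast-like and hypoblast-like cells. Where a cause is not named, the cause was not tested. Leaving out 1 embryo of 8 allows no p below 0.0571 in the exact tests of shares and values per embryo. Lost calls there say nothing about stability. The comparison of genes in epiblast-like cells could not be run under any alternative, since none gave enough such cells in 2 embryos of each day, and the all-barcode sums apply to whole embryos alone.

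The count of changed genes in whole embryos (2179) fell to 648 with thinned sums, which test fewer genes, to 1352 without predicted doublets and to 125 in cells under 1000 genes. With equal weight per cell it was 275, but that setting also replaced edgeR by limma on log2 of mean CPM plus 1. Its values, here and for genes below, therefore cannot be put down to the weighting alone. In trophoblast-like cells (980) it was 1637 with no low-count filter, 263 thinned, 569 with clustering centred within embryos and 61 in cells under 1000 genes. In hypoblast-like cells (1700) it was 673 thinned, 305 without predicted doublets and 38 in cells under 1000 genes. Genes whose day effect differed between classes (194) numbered 65 with DESeq2, 337 with no low-count filter, 337 with centred clustering and 382 with at least 5 cells per embryo. With 1 embryo left out the counts ran from 1346 (without day-12 embryo 4) to 2145, from 514 (without day-16 embryo 1) to 965, from 857 (without day-12 embryo 4) to 2049 and from 35 (without day-12 embryo 4) to 374 (without day-16 embryo 4). For the last, which rests on 2 embryos of each day, leaving 1 out leaves a single embryo of its day, so the range does not test stability.

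Lists called with a preset correlation numbered 0 of 37, 0 of 32 and 0 of 33 in whole embryos, trophoblast-like and hypoblast-like cells with an estimated correlation. In cells under 1000 genes they numbered 6, 4 and 5, where fewer lists could be tested, and 11 in hypoblast-like cells with at least 5 cells per embryo. With 1 embryo left out they ran from 18 to 21, from 10 to 11 and from 14 to 19.

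Changes in whole embryos that turned were of IFNT2 (0.55), to -0.27 with at least 500 genes per cell, -0.63 in cells from 1000 genes, -0.51 without embryos under 60% of UMIs in called cells and -0.35 without day-16 embryo 1 (0.83 without day-16 embryo 4). Over all barcodes it was 2.99 and passed. GATA3 (-0.31) turned to 0.36 with at least 100 genes per cell, 1.44 over all barcodes, 0.94 with equal weight and 0.015 without day-12 embryo 2 (-1.39 without day-16 embryo 1). IFNT (-0.56) turned to 1.28 in cells under 1000 genes, 1.68 over all barcodes, which passed, and 0.56 with equal weight. In cells from 1000 genes it was -1.38 and passed. PTGS2 (-0.97) turned to 0.89 over all barcodes and 0.48 with equal weight, and GATA6 (0.24) to -0.093 and -0.87. With equal weight per cell FOXA2 turned to -0.31, SOX17 to -0.44, and the called VGLL1 and IGF2R to 0.28 and -0.31. POU5F1 (-1.30) was at 0.10 without predicted doublets. With 1 embryo left out, POU5F1 ran from -4.13 to -0.54, SOX17 (1.197) from 0.36 to 2.01 and PTGS2 from -1.22 to -0.37.

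GATA2 in trophoblast-like cells (0.14) turned to -0.26 with no filter, -0.17 thinned, -0.12 with at least 100 genes, -0.21 with centred clustering, -0.16 in cells under and -0.089 in cells from 1000 genes, and -0.25 without day-16 embryo 4. In hypoblast-like cells FOXA2 (0.08) was at -0.017 with limma-voom, and from -0.33 to 0.44 with 1 embryo left out. SOX17 (-0.30) was at 0.27 with at least 500 genes and from -3.85 to 0.53 with 1 embryo left out. For the difference of classes AKR1D1 ran from -6.83 to 0.82 and SKAP1 from -5.33 to 1.31, both turned without day-16 embryo 1, where day 16 had a single embryo.

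GATA3 in trophoblast-like cells, not called, passed with at least 500 genes (1.27), centred clustering (1.08), cells from 1000 genes (1.33) and at least 5 cells per embryo (0.97). In whole embryos, with no low-count filter, POU5F1 (-1.495), PTGS2 (-1.14) and FOXA2 (1.13) passed. MT-ATP8 passed under 8 alternatives (-3.69 to -1.16), ND5 under 6 (-1.97 to -0.92) and MT-ND4 under 3 (-2.07 to -0.72), leaving aside left-out embryos. In hypoblast-like cells SOX17 (-2.60) and GATA6 (-1.006) passed with limma-voom, and PLIN2 (-1.60 to -0.997) and GADD45B (1.62 to 1.75) under 4 alternatives each. CTNNB1 passed in trophoblast-like cells with DESeq2 (0.75).

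The difference in median UMIs per cell (-242) was -901 with at least 500 genes, -49.0 with at least 100 genes and -26.2 without predicted doublets. That in median genes (-165) was -343, -51.2 and -39.2. That in mitochondrial share (-0.784 points) was -0.720, -0.831 and -0.482. With 1 embryo left out these ran from -282 to -181, from -191 to -134 and from -0.846 to -0.613, and the difference in called cells (83.5) from -21.8 (without day-16 embryo 1) to 139. The differences in share of cells ran from -36.2 to -16.1 points for trophoblast-like, -3.41 to 15.1 for hypoblast-like, -2.20 to -0.479 for epiblast-like and 15.3 to 26.5 for unnamed cells, and the difference in spread (0.101) from 0.0712 to 0.128. That difference was 0.0649 thinned to the smallest total, 0.0723 over all barcodes and 0.101 with the Pearson correlation.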

Other observations

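No test reported in this part was planned before the data were examined, and the test of markers outside called cells was written before its own values were seen but after the overall and interferon tau shares.

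Interferon tau RNA of day-16 embryos lay mostly outside called cells. Of the IFNT and IFNT2 UMIs of a library, 25.8% ± 14.5 lay outside called cells at day 12 and 87.0% ± 8.31 at day 16 (SD, n = 4, exact permutation p = 0.0286, the smallest possible), with 80.6% to 99.1% in the day-16 embryos. Over all barcodes the day-16 libraries held 4948 such UMIs, against 640 in called cells. The trophoblast marker UMIs other than these 2 genes lay outside called cells at 24.3% ± 4.17 and 55.8% ± 21.0 (SD, n = 4, exact permutation p = 0.0286), and the hypoblast marker UMIs at 16.2% ± 4.99 and 31.6% ± 12.1 (SD, n = 4, exact permutation p = 0.0857). KRT8 and KRT18 dominated the trophoblast markers, with 18709 and 16060 UMIs in trophoblast-like cells against 2554 for PTGS2, the next. In the 69-cell day-16 hypoblast-like cluster they also stood at 5635 and 2765 CPM, so the sum does not measure trophoblast RNA alone.

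A candidate explanation is that RNA was released from trophoblast-like cells of day-16 embryos before or during capture, so that trophoblast is under-represented among called cells. It was to show as a trophoblast marker share outside called cells more than 10 points above the hypoblast marker share in the day-16 embryos, and it did in 4 of 4, against 1 of 4 at day 12. The gap between the shares was 8.04 points ± 4.75 at day 12 and 24.2 points ± 13.4 at day 16 (SD, n = 4, difference 16.2, exact permutation p = 0.0571), which did not pass. The trophoblast share outside cells was close to that of all genes (51.0% ± 19.99 at day 16), so a hypoblast that was better kept in cells would give the same gap. Since the sum rested mostly on keratins shared by both classes, the gap does not isolate trophoblast RNA. Whether cells broke in the embryo, at dissociation or in the droplets was not tested.

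Few barcodes carried the class sums. In trophoblast-like cells 6, 7, 1 and 8 barcodes of the day-12 embryos and 21, 6, 3 and 21 of the day-16 embryos held at least 50% of the class's UMIs, and in hypoblast-like cells 2, 1, 2 and 3 and 8, 4, 3 and 11 did. Whether these barcodes were clumps of cells was not tested. A cluster of 56 cells, all of day 12, held 81.5% of the day-12 trophoblast-like UMIs, and a cluster of 69 cells, all of day 16, held 90.5% of the day-16 hypoblast-like UMIs. With predicted doublets removed and cells clustered again, the deepest trophoblast-like cluster had a median of 6419 UMIs, against 35468.5 for those 56 cells. The deepest hypoblast-like cluster then had a median of 24799 UMIs. Before, the deepest had 40417, in a cluster of 25 cells of which 24 were of day 12, and the 69 cells had 24390. Features without a symbol took 12.0% ± 0.944 of all UMIs of a library, in called cells or not, at day 12 and 17.8% ± 6.17 at day 16 (SD, n = 4, exact permutation p = 0.114).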
